A study of Mus musculus with 23 samples.

How the data were processed

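RNA from the hippocampus of male C57BL/6 mice was sequenced by the authors in 23 libraries, 8 from fathers and 15 from offspring. Per the labels' protocols, 500 ng of total RNA was enriched for mRNA with oligo-dT beads and made into strand-specific libraries with the TruSeq Stranded mRNA kit, with 15 PCR cycles. Sequencing on a HiSeq2000 gave paired reads of 76 bases, per the labels' protocols. The submitters' processing notes name STAR 2.5.2a, RSEM 1.2.28, DESeq2 1.10 and the mouse build GRCm38, without saying which step each served. The annotation version, the filters and whether counting used the strand are not given in the sources used here. The file titles say that an outlier was left out, without naming it.

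The authors deposited 1 table of normalized counts for the fathers and another for the offspring. The values are a signal on the scale of counts, made by the authors by dividing gene counts by 1 size factor per library, as read from the values. In each column the value of 1 read was estimated from the smallest value and refined by least squares. Dividing by it gave a number within 0.1 of a whole number for 100% of the values above 0 in every library. Each library's median ratio to the geometric mean over all 23 libraries lay between 1.0026 and 1.0061, so both tables share 1 scale. The authors also deposited 2 comparison tables with log2 fold changes of exercised over sedentary groups, moderated and unmoderated, standard errors, p-values and adjusted p-values, per the file headers. The mean expression column was identical in both tables, and differed by over 1 percent from the mean of the 23 libraries for 4504 of the 14247 genes with a mean above 50. Gene ontology tables deposited by the authors give a fold enrichment ratio, a p-value and a Benjamini-adjusted p-value per term, per the file headers.

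Of the 51912 gene identifiers in the tables, 47648 had the same versioned identifier in the GENCODE M21 annotation of GRCm38, and 51633 matched when the version was ignored. Coordinates come from that annotation, and GC content and length are those of the longest transcript. Of the 75 genes named by rule, 12 overlap another gene on the same strand, and for Chml and Adat3 that gene is protein-coding. The read assignment of overlapping genes is uncertain, as is that of genes with near-identical copies, such as hemoglobin and ribosomal protein genes.

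Groups were taken from the labels, and replicate numbers only name libraries within a group. The labels do not state that each library is a separate animal, nor which father or litter each of the offspring came from. All p-values therefore measure only the spread between these samples, which may be partly technical. All 61 pairs of libraries within a group were compared by a chi-square test on genes with at least 20 reads summed over the pair. The chi-square divided by its degrees of freedom lay between 5.99 and 66.7, so no pair agreed within sampling noise. A pair of offspring libraries with the same barcode label gave 30.5, and both were kept. The labels give no sequencing date. The barcodes of exercised fathers replicate 4 and of replicates 7 and 8 of the offspring of sedentary fathers come from another number series, AD21, which holds 1 group in each generation. No value within that series could be computed, and fits without those libraries were run.

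Recovered reads ranged from 40124885 to 55172616 per library in the fathers and from 33667580 to 50746570 in the offspring. PCR reads without molecular identifiers are not independent molecules, so read numbers overstate the precision they give.

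The tests, the gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. Exercised and sedentary groups were compared within each generation with limma 3.58.1 in R 4.3.3, on log2(normalized count + 1), with empirical Bayes moderation and a mean-variance trend. Genes entered with a normalized count of at least 10 in at least 4 libraries of the fathers or 7 of the offspring. Fold changes are on this log2 scale, which understates the change of genes with low counts. The Benjamini-Hochberg adjusted p threshold was 0.05, and tests were two-sided. Gene lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the 30 lists. Each list was tested again with camera at an estimated correlation, with fry, and with an exact permutation of the list mean over libraries. Where members are counted as passing "adjusted over the list alone", the adjustment ran over that list's members.

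The lists were immediate early genes, neurotrophins and growth factors, adult neurogenesis, nuclear respiratory chain, mitochondrially encoded mRNAs, citric acid cycle, mitochondrial biogenesis and dynamics, ribosomal proteins, glutamatergic synapse, GABAergic interneurons, glucocorticoid response, heat shock and protein folding stress, circadian clock, DNA methylation and histone modifiers, and imprinted genes. Markers of cell types or neighboring tissue comprised dentate granule cells, CA1 pyramidal cells, CA2 and CA3 pyramidal cells, astrocytes, oligodendrocytes and myelin, oligodendrocyte precursors, microglia, endothelial cells, mural cells, meningeal fibroblasts, choroid plexus, thalamus and habenula, striatum, neocortex, and erythrocytes.

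Named genes were the 10 higher and 10 lower genes past the threshold with the largest log2 fold change or, when fewer than 10 passed, the 5 higher and 5 lower genes with the smallest p. To these were added Bdnf, Vegfa, Igf1, Dcx, Cs, Ppargc1a, Arc and Fos, the 3 members with the smallest p in the direction of each list that passed, and the 10 genes with the smallest adjusted p in the authors' deposited table. Predicted genes were passed over. Other genes named in the text were chosen after their values were seen.

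Fold changes of both generations were compared by Pearson's correlation over the genes tested in both, with an exact permutation over the 70 labelings of the fathers. The 100 genes with the smallest p in each direction in the fathers were tested as sets with camera in the offspring. These comparisons share no libraries.

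The code was tested on simulated counts in which 200 genes were changed. Each gene was drawn independently, so the simulation lacked differences between libraries that many genes share. For the fathers, limma recovered 13, 30, 38 and 46 of 50 genes changed 1.25, 1.5, 2 and 3-fold among 17493 simulated genes, with 6 false calls. In the offspring simulation of 17522 genes it recovered 26, 41, 45 and 50 of 50 at those sizes, with 9 false calls. DESeq2 recovered 23, 33, 42 and 44 of 50 in the fathers' simulation and 33, 42, 45 and 50 in the offspring's. It made 38 false calls among 17293 unchanged genes in the fathers' simulation and 22 among 17322 in the offspring's, and edgeR made 7 and 10.

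Alternatives were other pseudocounts, filters and scalings, array weights, robust moderation, a choroid plexus covariate, leaving out each library, averaging or blocking libraries that share a title stem, and count tests on the recovered reads with edgeR 4.0.16 and DESeq2 1.42.0. Added after seeing the data were covariates for the thalamus and habenula list, fits without libraries that stood apart in marker genes, removal of GC content and length trends, the exact permutation of list means, and a DESeq2 fit over all 23 libraries. All 35 splits of the fathers and 100 drawn splits of the offspring, the real ones included, were refitted. The authors' lists of called genes were not used here beyond their full comparison tables.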

Results

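Hippocampal mRNA was sequenced in 23 libraries from male mice of C57BL/6, an inbred laboratory strain, over 2 generations. The first generation comprised 4 exercised fathers, which ran on a treadmill for 40 minutes a day over 6 weeks, and 4 sedentary fathers without access to exercise, all killed at 7 months. The second comprised 7 offspring of exercised fathers and 8 offspring of sedentary fathers, killed at 5.5 months. Libraries held 45401036 ± 2964997 reads in the exercised fathers (SD, n = 4) and 47495546 ± 7489158 in the sedentary fathers (n = 4). They held 43626664 ± 3256836 reads in the offspring of exercised fathers (n = 7) and 42555348 ± 6578098 in the offspring of sedentary fathers (n = 8). The 10 most abundant genes took between 8.02% and 10.6% of the reads of a library. Values are the authors' normalized counts, and fold changes are log2 of exercised over sedentary.

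The first comparison asked how hippocampal gene expression in exercised fathers differed from that in sedentary fathers. Genes of the choroid plexus, the tissue that secretes cerebrospinal fluid, had the largest mean difference of the 30 lists, with all 16 members higher on average in the exercised fathers. Their list mean was 10.16 ± 0.79 in exercised fathers (SD, n = 4) and 8.61 ± 2.29 in sedentary fathers (n = 4), a mean log2 difference of 1.56. Genes of the thalamus and habenula, which lie next to the hippocampus, went the other way, at 8.20 ± 0.50 (SD, n = 4) against 9.02 ± 1.1 (n = 4), with 10 of 12 members lower. Ribosomal protein, glucocorticoid response and GABAergic interneuron genes had higher means, and markers of endothelial cells, mural cells, meningeal fibroblasts and erythrocytes had lower means. No single gene passed with limma. These 9 lists passed camera at a preset correlation but had an adjusted p = 0.824 with an estimated correlation.

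Of 17493 genes tested in the fathers, 0 passed with limma. At an unadjusted p under 0.05 there were 1402 genes, 777 of them higher and the rest lower, and the smallest adjusted p was 0.539. The count test of edgeR on the recovered reads called 0 genes, with 1434 at an unadjusted p under 0.05. DESeq2 called 66, 33 in each direction, with 1339 at an unadjusted p under 0.05. On simulated data of this size, with 200 genes changed and each gene drawn independently, 38 of DESeq2's 180 calls were false. That share need not hold for the real data. Without exercised replicate 2 or without sedentary replicate 4, limma called 1 predicted gene. The median gene had a standard error of 0.08 on the log2 scale, and the median absolute log2 fold change was 0.07.

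The 5 higher genes with the smallest p included a pair of neuropeptides of inhibitory neurons. Sst, which encodes somatostatin (ENSMUSG00000004366.3, GRCm38 chromosome 16, 23889573 to 23890958), had 6550 ± 264 normalized counts in exercised fathers (SD, n = 4) and 5628 ± 172 in sedentary fathers (n = 4). Its log2 fold change was 0.22 (SE 0.04, limma adjusted p = 0.539). Npy, which encodes neuropeptide Y (ENSMUSG00000029819.6, chromosome 6, 49822710 to 49829507), had 1215 ± 54.9 and 1025 ± 51.3 (log2 fold change 0.25, SE 0.05). Cyp4f15, a cytochrome P450, Cnih2, an auxiliary subunit of AMPA receptors, and Itpka, a kinase of inositol trisphosphate, had log2 fold changes of 0.31, 0.21 and 0.20. The 5 lower genes included Rgs17 and Rgs4, regulators of G protein signaling, at -0.21 (SE 0.04) and -0.28 (SE 0.05). Olfm3 stood at -0.33, and Chml, which overlaps Opn3 on the same strand, at -0.36. Nr3c1, the glucocorticoid receptor (ENSMUSG00000024431.14, chromosome 18, 39410545 to 39519421), had 4728 ± 91.5 normalized counts in exercised and 5276 ± 78.3 in sedentary fathers (SD, n = 4 each; log2 fold change -0.16, SE 0.03). All 10 genes had a limma adjusted p of 0.539. DESeq2 on the fathers alone put each of them under its threshold, with adjusted p between 0.000423 for Rgs17 and 0.0266 for Cyp4f15 and Npy. A DESeq2 fit over all 23 libraries, added after seeing the data, called none of the 10 and called 5 genes in all. These were Chrnb3, Irx2 and Vav3, all lower, and 2 predicted genes, with 1123 at an unadjusted p under 0.05. Over all alternatives the adjusted p of Rgs17 reached 0.916. The log2 fold changes nearest 0 under any alternative were -0.12 for Rgs17, -0.16 for Olfm3 and 0.12 for both Cnih2 and Itpka. The median GC content of all genes tested in the fathers was 49.4%. All 5 higher genes lay above it and all 5 lower genes below it. With the GC trend removed, an alternative added after seeing the data, no gene had a limma adjusted p below 0.915. GC content differences between libraries may account for part of these 10 fold changes, and were not told apart from exercise.

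Among genes followed in exercise studies, the growth factor Bdnf differed by 0.02 (SE 0.09, limma adjusted p = 0.957) and Vegfa by -0.04 (SE 0.08). Igf1 had 375 ± 45.6 normalized counts in exercised and 455 ± 34.9 in sedentary fathers (SD, n = 4 each; log2 fold change -0.28, limma adjusted p = 0.556). Dcx, a marker of immature neurons, differed by -0.02 (SE 0.09), citrate synthase Cs by -0.03 (SE 0.04) and Ppargc1a, a regulator of mitochondrial biogenesis, by -0.09 (SE 0.04). The activity-regulated gene Arc had 4074 ± 774 and 3055 ± 226 (log2 fold change 0.40, SE 0.11, limma adjusted p = 0.539), and Fos had 274 ± 95.7 and 259 ± 60.4 (0.05, SE 0.23). None of these 8 genes passed. The estimates of Bdnf, Vegfa, Dcx, Cs and Fos changed sign when single libraries were left out, reaching -0.04 for Bdnf without sedentary replicate 4, 0.02 for Vegfa without exercised replicate 3, 0.05 for Dcx without sedentary replicate 2, 0.0020 for Cs without exercised replicate 1 and -0.17 for Fos without exercised replicate 2.

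Of the 30 lists, 9 passed camera at the preset correlation, 4 higher and 5 lower in exercised fathers. With an estimated correlation 0 passed, and the adjusted p = 0.824 with an estimated correlation was the same for all 9. By fry 0 passed, with a smallest adjusted p of 0.682. By exact permutation of list means the smallest adjusted p was 0.725, but 4 against 4 libraries cannot give a p below 0.0286, so no list could pass after adjustment over the 30 lists unless most of them reached that p. No member of any list passed over all genes tested with limma. DESeq2 on the fathers alone put list members such as Sst, Npy, Dlx1 and Rps2 under the threshold (adjusted p = 0.00118, 0.0266, 0.0454 and 0.0183).

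For the choroid plexus list, camera gave an adjusted p of 0.000900 and the exact permutation p was 0.314. None of the 16 members had an unadjusted p under 0.05. Examples were the transporter Slc4a5 (log2 fold change 2.29), the folate receptor Folr1 (1.77, SE 1.02) and the water channel Aqp1 (2.07, SE 1.17). The spread lay within the sedentary group, where list means were 6.07 and 7.32 in replicates 1 and 2 and 10.94 and 10.09 in replicates 3 and 4, while exercised fathers ranged from 9.27 to 11.10. Transthyretin, Ttr, the most abundant member, had 770 normalized counts in sedentary replicate 1 and 163326 in sedentary replicate 3. Without sedentary replicates 1 and 2, a fit added after seeing the data, the list's mean difference was -0.35 and camera turned to the lower direction (adjusted p = 0.0859). Without sedentary replicates 3 and 4, added likewise, the mean difference was 3.47 (adjusted p = 1.01e-16), and Slc4a5 (4.83) and Folr1 (3.85) passed over all genes with limma (adjusted p = 0.0478 for both). Both fits left out libraries that stood apart in this list's own values, so their p-values are no independent evidence here. Over the alternatives at the preset correlation the list's adjusted p ran from 1.01e-16 to 0.991, and the adjusted p = 0.824 with an estimated correlation. The value of 0.991 came from a fit with this list's own mean as a covariate, which removes the list's difference by construction.

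For the thalamus and habenula list, the mean difference was -0.82 (camera adjusted p = 0.00834, exact permutation p = 0.229), with 2 of 12 members lower at an unadjusted p under 0.05. Rora, a nuclear receptor abundant in thalamus, had 2926 ± 135 normalized counts in exercised and 4224 ± 1347 in sedentary fathers (SD, n = 4 each). The transcription factor Lef1 had a log2 fold change of -0.72 (SE 0.32) and Slc17a6, the vesicular glutamate transporter of thalamic neurons, of -0.53 (SE 0.25). List means were 9.43 and 10.26 in sedentary replicates 3 and 4, above the 7.58 to 8.72 of the other 6 fathers. Without those replicates, also a fit added after seeing the data, the mean difference was 0.00059 (adjusted p = 0.772). Without sedentary replicates 1 and 2 it was -1.65 (adjusted p = 3.09e-11), and Rora passed over all genes with limma (log2 fold change -0.86, adjusted p = 0.0267). That fit kept only the sedentary libraries highest in this list, so its p-values are no independent evidence on the list or Rora. Camera's adjusted p was 0.108 without sedentary replicate 3, 0.195 without sedentary replicate 4 and 0.101 without exercised replicate 2 and 0.0757 with array weights, and ran from 3.09e-11 to 0.793 over the alternatives at the preset correlation. For this list the adjusted p = 0.824 with an estimated correlation.

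**Figure D1:**
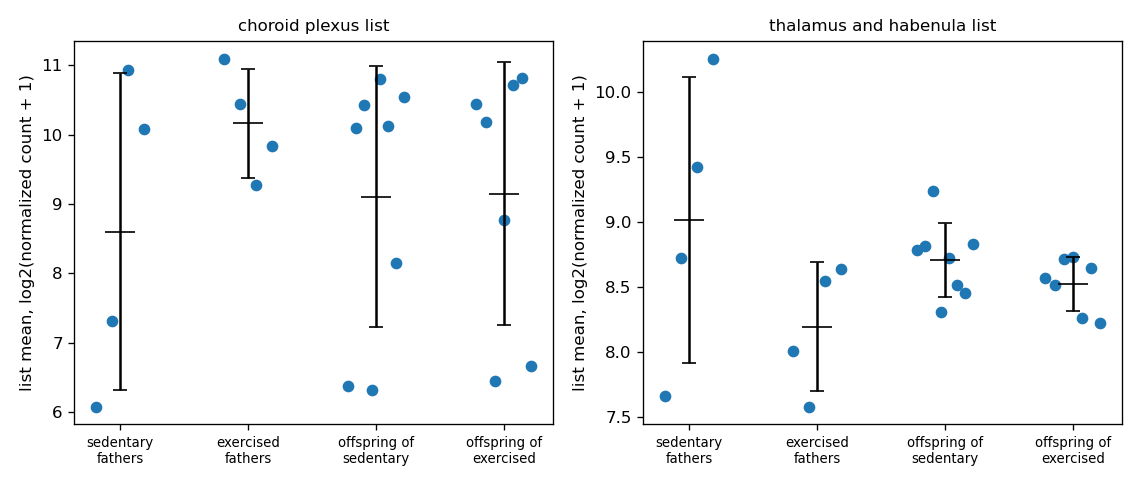
Mean log2(normalized count + 1) of the choroid plexus list (left) and the thalamus and habenula list (right) in each library, with the group mean and SD as bars. In the sedentary fathers the choroid plexus mean ran from 6.07 to 10.94, and the thalamus and habenula mean was 9.43 and 10.26 in 2 libraries against 8.72 or less in the other fathers.

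Ribosomal proteins had 66 of 81 members higher with a mean difference of 0.03 (camera adjusted p = 0.00157). Their leading members were Rps2 at 0.15 (SE 0.04), Rpl10a at 0.11 and Rps28 at 0.11, and 4 members had an unadjusted p under 0.05. The SD of the list mean, 0.04 among exercised and 0.05 among sedentary libraries, exceeded that difference. Camera's adjusted p was 0.0944 without exercised replicate 1, 0.102 without sedentary replicate 1 and 0.0573 without sedentary replicate 3. It was 0.126 with the choroid plexus covariate, 0.0620 without sedentary replicates 1 and 2 together, 0.0589 with array weights and 0.151 with the length trend removed, the largest at the preset correlation. The smallest was 1.08e-05.

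The glucocorticoid response list had 11 of 14 members higher (mean 0.19, camera adjusted p = 0.00834). Examples were Fkbp5, a co-chaperone induced by glucocorticoids, at 0.20 (SE 0.06), Plin4, a lipid droplet protein, at 0.78 (SE 0.27) and the clock gene Per1 at 0.15 (SE 0.05). Plin4 ran from 0.48 to 0.94 with a library left out. The list's exact permutation p of 0.0286 was the smallest that 4 against 4 libraries can give, and 0.725 when adjusted over the lists. Camera's adjusted p was 0.0573 without sedentary replicate 3, 0.0741 without sedentary replicates 3 and 4 together and 0.0554 with the thalamus and habenula covariate, within a range from 0.00200 to 0.0741 over the alternatives at the preset correlation.

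GABAergic interneuron genes had 11 of 16 members higher (mean 0.07, camera adjusted p = 0.0446). Of these, 3 passed with limma adjusted over the list alone, namely Sst, Npy and the transcription factor Dlx1 (0.35, SE 0.08), and 0 over all genes tested. DESeq2 on the fathers alone put all 3 under the threshold over all genes tested (adjusted p = 0.00118, 0.0266 and 0.0454). Camera's adjusted p was 0.139, 0.103 and 0.177 without exercised replicates 2, 3 and 4, and 0.108 and 0.195 without sedentary replicates 3 and 4. It was 0.549 without the last pair together, 0.322 with the thalamus and habenula covariate, 0.1051 with array weights, 0.0660 with the filter at 50, 0.0628 with quantile normalization and 0.0648 with the length trend removed. The smallest of all alternatives was 0.00134. For these 3 lists the adjusted p = 0.824 with an estimated correlation.

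Vascular and border cell markers were lower. Endothelial cells had 11 of 12 members lower (mean -0.16, camera adjusted p = 0.00655), among them the adhesion gene Cdh5 at -0.34 (SE 0.11) and the receptors Tek at -0.23 (SE 0.09) and Flt1 at -0.22 (SE 0.08). Mural cells had all 8 members lower (mean -0.26, adjusted p = 0.0265), with Rgs5 at -0.19, Abcc9 at -0.19 and the receptor Pdgfrb at -0.10. Meningeal fibroblasts had 11 of 12 members lower (mean -0.46, adjusted p = 0.0446), led by Dcn at -0.55, Aldh1a2 at -1.04 and the collagen gene Col3a1, whose mean ratio on this scale was 0.465. Log2 fold changes with a library left out ran from -0.75 to -0.28 for Dcn, from -1.56 to -0.72 for Aldh1a2 and from -1.66 to -0.58 for Col3a1. Erythrocyte genes had all 5 members lower (mean -0.88, adjusted p = 0.0207), with the hemoglobins Hba-a2 at -1.03 (SE 0.44), Hbb-bt at -1.05 and Hbb-bs at -0.77. Each of these 4 lists had an adjusted p = 0.824 with an estimated correlation.

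The calls of these 4 lists depended on single libraries. Without exercised replicate 1, camera's adjusted p was 0.0944 for endothelial cells, 0.182 for mural cells, 0.201 for meningeal fibroblasts and 0.131 for erythrocytes. Without sedentary replicate 3 these values were 0.0573, 0.108, 0.345 and 0.09996, and without sedentary replicate 4 they were 0.154, 0.195, 0.233 and 0.195. Without exercised replicate 4 they were 0.0920 for endothelial cells, 0.152 for mural cells and 0.296 for meningeal fibroblasts. Meningeal fibroblasts also lost the call without exercised replicate 2 (0.0951) or sedentary replicate 1 (0.0834). Sedentary replicates 3 and 4 had the highest means of the thalamus and habenula list. Without both together, the adjusted p was 0.486, 0.631, 0.920 and 0.680 in the same order, and camera's direction for meningeal fibroblasts turned. In that order it was 0.192, 0.368, 0.461 and 0.459 with the thalamus and habenula covariate and 0.270, 0.447, 0.407 and 0.648 with the choroid plexus covariate as well. With array weights it was 0.182 for endothelial cells, 0.260 for mural cells and 0.192 for erythrocytes. Meningeal fibroblasts also lost the call with median centring (0.0789), without the filter (0.0589) and with the length trend removed (0.0654). The smallest adjusted p over all alternatives was 1.70e-05 for endothelial cells and meningeal fibroblasts, 0.000420 for mural cells and 0.000356 for erythrocytes, and the largest for meningeal fibroblasts was 0.979 with array weights, where their mean difference was 0.0056.

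The other 21 lists did not pass in the fathers. Those nearest the threshold were the nuclear respiratory chain (mean 0.03, camera adjusted p = 0.0624), neocortex (-0.18, 0.112), CA1 pyramidal cells (0.07, 0.112), microglia (0.04, 0.115) and mitochondrially encoded mRNAs (-0.07, 0.196). At the preset correlation the nuclear respiratory chain passed in the higher direction without exercised replicate 1 (adjusted p = 0.0488), exercised replicate 3 (0.0289) or sedentary replicate 4 (1.94e-05), and with the thalamus and habenula covariate (4.67e-07). In the main fit its estimated correlation was 0.479, and camera's adjusted p with it was 0.881. CA1 pyramidal cells passed in the higher direction without exercised replicate 1 (0.0251) or sedentary replicate 1 (0.0298), and oligodendrocytes and myelin in the lower direction without the same libraries (0.0419 and 0.0437). Neocortex passed lower without sedentary replicate 1 (0.0295), mitochondrially encoded mRNAs lower without exercised replicate 1 (0.00301) and microglia higher without exercised replicate 2 (0.0252). Adult neurogenesis genes averaged 0.18 (adjusted p = 0.333), but their median was 0.03, with 11 members higher and 8 lower. Immediate early genes averaged 0.04 (0.359), neurotrophins and growth factors 0.08 (0.528), and the circadian clock 0.05 (0.307), where 2 of 15 members passed adjusted over the list alone. Those were the repressor Cry2 at 0.12 (SE 0.03) and Hlf at -0.14 (SE 0.04). The CA2 and CA3 list had 2 members passing in that way, Rgs14 at 0.18 (SE 0.05) and Bok at 0.24 (SE 0.07). Its median was -0.01 and its mean 0.02, with camera in the higher direction (adjusted p = 0.799). Means were -0.05 for oligodendrocytes and myelin (0.307), 0.04 for astrocytes (0.307), 0.04 for heat shock and protein folding stress (0.502), 0.02 for DNA methylation and histone modifiers (0.611) and 0.03 for striatum (0.731). They were 0.07 for imprinted genes (0.799), 0.01 for the citric acid cycle (0.884) and -0.01 for oligodendrocyte precursors (0.956). Mean, median and test differed in sign for 3 more lists, all near 0. Glutamatergic synapse had a median of -0.00034, a mean of 0.00034 and camera in the higher direction (0.715). This list passed camera in that direction with the choroid plexus covariate (adjusted p = 0.0210). It also did without sedentary replicates 1 and 2 (0.00255), a fit added after seeing the data. Mitochondrial biogenesis and dynamics had a median of 0.01, a mean of -0.01 and the lower direction (0.748). Dentate granule cells had a median and mean of 0.01 and the lower direction (0.956).

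The authors' deposited table of the fathers called 21 genes at an adjusted p under 0.1, 1 higher and 20 lower in exercised fathers, and 14 of them under 0.05. The 10 with the smallest adjusted p were Slc6a3, Alb, Shox2, Chrnb3, Irx2, Chrna3, Pou4f1, Tnnt1, Atp2a1 and Abhd12b. Shox2, Irx2 and Pou4f1 are developmental transcription factors, and Chrnb3 and Chrna3 are nicotinic acetylcholine receptor subunits. Chrnb3 (ENSMUSG00000031492.13, chromosome 8, 27368711 to 27399730) had 18.2 ± 4.79 normalized counts in exercised and 77.1 ± 49.5 in sedentary fathers (SD, n = 4 each; log2 fold change -1.81, SE 0.44, limma adjusted p = 0.539). Shox2 (ENSMUSG00000027833.16, chromosome 3, 66971727 to 66981771) had 29.7 ± 22.8 and 344 ± 415 (-2.36, SE 1.29), and Irx2 had 6.50 ± 3.57 and 51.8 ± 35.3 (-2.34, SE 0.86). The log2 fold changes of Chrna3, of the calcium pump gene Atp2a1 and of Tnnt1, a muscle troponin gene, were -1.23, -1.85 and -1.19. Estimates with a library left out ran from -1.79 to -0.60 for Chrna3 and from -2.50 to -1.31 for Atp2a1. They ran from -1.93 to -0.39 for Tnnt1 and from -3.68 to -1.38 for Shox2. For Slc6a3, the dopamine transporter, the authors' deposited table gave an unmoderated log2 ratio of -3.24 and an adjusted p of 6.69e-05. Here Slc6a3 had 479 normalized counts in sedentary replicate 4, between 3.39 and 14.4 in the other sedentary libraries, and between 6.26 and 18.1 in the exercised fathers. Pou4f1 had 158 in sedentary replicate 2, 22.2 or less in the other sedentary libraries and up to 16.1 in exercised fathers. Alb, albumin, had 94.0 in sedentary replicate 1, 22.0 in sedentary replicate 2 and 2.68 or less in the other fathers. Of the 21 genes 13 met the filter used here, and Alb, Pou4f1 and Abhd12b did not. All 13 had the same sign as in the authors' deposited table, 7 had an unadjusted p under 0.05, and 0 passed with limma.

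**Figure D2:**
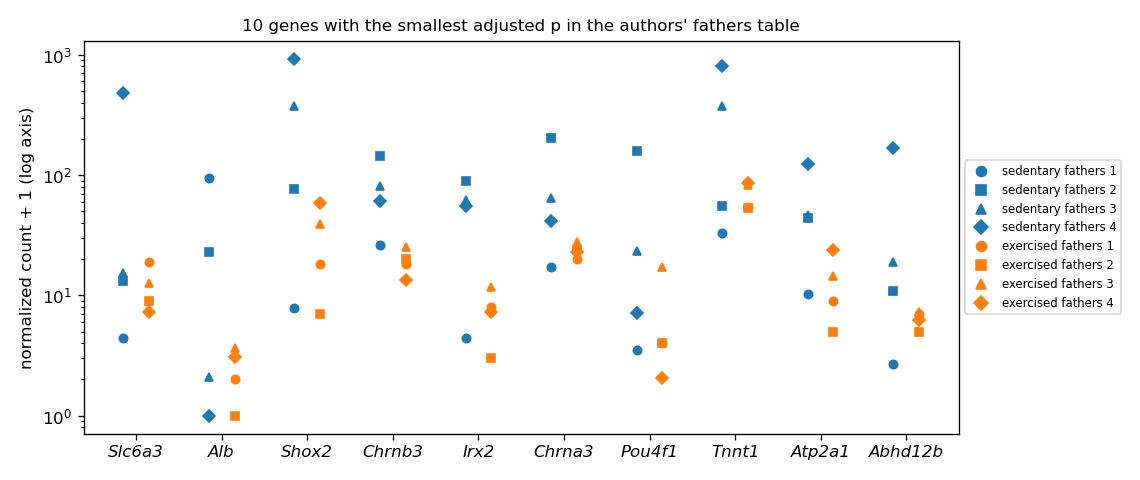
Normalized count + 1 (log axis) of the 10 genes with the smallest adjusted p in the authors' deposited table of the fathers, with 1 point per library, sedentary in blue and exercised in orange. Single sedentary libraries stood above the rest for Slc6a3 (479 in replicate 4) and Pou4f1 (158 in replicate 2).

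Of the 20 lower genes, the highest library was sedentary replicate 4 for 10 genes, Slc6a3, Shox2 and Tnnt1 among them. It was sedentary replicate 2 for 8, among them Chrnb3, Chrna3, Irx2 and Pou4f1. The 20 genes thus peaked in different libraries. Sedentary replicate 2 was not among the libraries with the highest means of the thalamus and habenula list. Chrnb3, Chrna3, Irx2 and Pou4f1 are not members of that list, so its mean does not tell whether replicate 2 held tissue that expresses them. Without sedentary replicate 4 the Slc6a3 estimate turned to 0.22, and with the thalamus and habenula covariate, added after seeing the data, Slc6a3 and Tnnt1 turned to 0.41 and 0.22. The authors' deposited enrichment table listed regulation of muscle contraction (3 genes, 124-fold, Benjamini-adjusted p = 0.0652), cholinergic synaptic transmission (3 genes, 95.2-fold, 0.0561) and the response to nicotine (3 genes, 63.5-fold, 0.0831) with the smallest p-values.

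The second comparison asked whether hippocampal expression differed between offspring of exercised and of sedentary fathers. The heat shock and protein folding stress list had a lower mean in the offspring of exercised fathers, with the estimates of all 12 members below 0 (mean log2 difference -0.17). Camera gave this list an adjusted p = 0.00403 at the preset correlation and an adjusted p = 0.922 with an estimated correlation, and none of its members passed with limma. The list mean was 11.81 ± 0.09 in offspring of exercised fathers (SD, n = 7) and 11.97 ± 0.23 in offspring of sedentary fathers (n = 8). Its leading members act in the endoplasmic reticulum: the chaperone Hspa5 (log2 fold change -0.32, SE 0.13), the disulfide isomerase Pdia4 (-0.26, SE 0.11) and Sdf2l1 (-0.35, SE 0.17). Endothelial markers also had estimates below 0 in all 12 members (mean -0.10), with list means of 9.48 ± 0.10 (SD, n = 7) and 9.58 ± 0.07 (n = 8). Their camera adjusted p = 0.0329 became an adjusted p = 0.922 with an estimated correlation. No single gene passed with limma, and choroid plexus list means were 9.15 ± 1.90 (SD, n = 7) and 9.11 ± 1.88 (n = 8).

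Of 17522 genes tested in the offspring, 0 passed with limma, with 1726 at an unadjusted p under 0.05, 765 higher and 961 lower, and a smallest adjusted p of 0.311. With edgeR 0 were called, with 1650 at an unadjusted p under 0.05. DESeq2 called 48, 29 higher and 19 lower. On simulated data of this size, with 200 genes changed and each gene drawn independently, 22 of its 192 calls were false, which need not hold for the real data. In a DESeq2 fit over all 23 libraries, added after seeing the data, 91 were called, 44 higher and 47 lower. These tests treated all libraries as independent, though some libraries of the offspring of exercised fathers shared a title stem.

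The higher genes with the smallest p were Adat3, Tmem175, a lysosomal potassium channel, the sodium channel subunit Scnn1a, the ciliary rootlet gene Crocc and the zinc finger gene Zfp628. Adat3, which encodes a subunit of a transfer RNA editing enzyme (ENSMUSG00000113640.1, chromosome 10, 80602880 to 80607654), had 38.6 ± 8.15 normalized counts in offspring of exercised fathers (SD, n = 7) and 21.2 ± 4.80 in offspring of sedentary fathers (n = 8), a log2 fold change of 0.84 (SE 0.17, limma adjusted p = 0.311). This entry lies inside Scamp4 on the same strand and overlaps another entry of the same symbol (ENSMUSG00000035370.9), whose log2 fold change was -0.08 (SE 0.15), so the assignment of reads among them is uncertain. Tmem175 (ENSMUSG00000013495.15, chromosome 5, 108629770 to 108648782) had 1078 ± 42.8 and 951 ± 39.1 (0.18, SE 0.04). Scnn1a, Crocc and Zfp628 had log2 fold changes of 0.24, 0.26 and 0.22. The lower genes were led by Acer2, an alkaline ceramidase (ENSMUSG00000038007.14, chromosome 4, 86874396 to 86934822), with 221 ± 17.9 (SD, n = 7) against 308 ± 37.1 (n = 8), a log2 fold change of -0.47 (SE 0.08, limma adjusted p = 0.311). It passed with array weights (adjusted p = 0.0319) and without replicate 1 of the offspring of sedentary fathers (adjusted p = 0.0141), the smallest of its alternatives, of which the largest was 0.998. The circadian repressor Cry1 (ENSMUSG00000020038.10, chromosome 10, 85131700 to 85185064) had 580 ± 51.7 and 692 ± 37.8 (-0.26, SE 0.06). Slc46a3, Rnf115 and the histone demethylase Kdm7a had log2 fold changes of -0.25, -0.17 and -0.32, the last with an adjusted p of 0.320. DESeq2 on the offspring alone gave an adjusted p of 0.00696 for Tmem175 and Crocc, 0.0113 for Rnf115 and 0.0139 for Kdm7a. In the DESeq2 fit over all 23 libraries these 4 passed too, as did Cry1 (0.00901), Zfp628 (0.0168) and Scnn1a (0.0320). Over all alternatives the adjusted p of each of these 7 genes reached 0.998.

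Of the genes followed in exercise studies, Vegfa had 1720 ± 125 normalized counts in offspring of exercised fathers (SD, n = 7) and 1966 ± 175 in offspring of sedentary fathers (n = 8), a log2 fold change of -0.19 (SE 0.06, limma adjusted p = 0.381). Igf1 differed by -0.17 (SE 0.09, limma adjusted p = 0.527), and Bdnf, Dcx, Cs and Ppargc1a by 0.02, 0.02, 0.01 and 0.02. Arc, at 6554 ± 2698 and 6704 ± 2785, and Fos, at 807 ± 460 and 802 ± 506, varied more between libraries of a group than between groups. None of these 8 passed.

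Of the 30 lists, 2 passed camera at the preset correlation in the offspring, both lower. Heat shock and protein folding stress had an adjusted p of 0.00403 and an exact permutation p of 0.0998, and 2 of its 12 members had an unadjusted p under 0.05. Endothelial cells had an adjusted p of 0.0329 and an exact permutation p of 0.0510, and 2 members passed adjusted over the list alone, Adgrl4 at -0.24 (SE 0.07) and Flt1 at -0.23 (SE 0.08). The next member was Ly6c1 at -0.14 (SE 0.06). Both lists had an adjusted p = 0.922 with an estimated correlation, and 0 lists passed by fry or by exact permutation (smallest adjusted p = 0.483 and 0.773). The heat shock list kept its call without each of the 15 libraries in turn and with camera under each of 17 other settings. For endothelial cells camera's adjusted p was 0.0862, 0.0602, 0.0997 and 0.182 without replicates 3, 4, 5 and 6 of the offspring of exercised fathers, and 0.117 and 0.0944 without replicates 3 and 6 of the offspring of sedentary fathers. It was 0.0871 with libraries of the same title stem averaged, 0.0612 with the filter at 50 and 0.0674 with the choroid plexus and the thalamus and habenula covariates together, so the call also ended there. The smallest over all its alternatives was 0.000252.

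The other 28 lists did not pass in the offspring. Oligodendrocyte and myelin genes had 14 of 16 members lower (mean -0.08, camera adjusted p = 0.0901), and the nuclear respiratory chain (0.03), neurotrophins and growth factors (-0.06), thalamus and habenula (-0.19) and the circadian clock (-0.05) each had an adjusted p of 0.148. In the clock list 6 of 15 members were lower at an unadjusted p under 0.05, and Cry1 passed adjusted over the list alone. Microglia (-0.04), the glucocorticoid response (-0.07) and ribosomal proteins (0.02) had an adjusted p of 0.177. The nuclear respiratory chain and ribosomal proteins passed in the higher direction with libraries of the same title stem averaged (adjusted p = 0.0125 for both), with the title stem as a block (0.0135 and 0.0150), with quantile normalization (0.0112 and 0.0387) and without the AD21 barcode series (1.21e-06 and 1.95e-06). Without the 5 libraries low in choroid plexus genes, a fit added after seeing the data, both passed in the lower direction (0.00170 and 5.19e-06). Leaving out replicate 1 or 2 of the offspring of exercised fathers, or replicate 7 or 8 of the offspring of sedentary fathers, also gave both lists a call in the higher direction, with adjusted p between 0.000377 and 0.0185. All these calls used the preset correlation of 0.01, while the estimated correlations in the main fit were 0.788 and 0.821. With those, both lists had an adjusted p of 0.985, and their exact permutation p was 0.683 and 0.748. Oligodendrocytes and myelin passed in the lower direction without replicate 2 (0.0381) or 6 (0.00312) of the offspring of exercised fathers and without replicate 2 (0.0151), 7 (0.0204) or 8 (0.0239) of the offspring of sedentary fathers. The circadian clock did without replicate 2 of the offspring of exercised fathers (0.0381), and thalamus and habenula without replicate 4 of the offspring of sedentary fathers (0.0245). Glutamatergic synapse (-0.04, 0.271) had 1 member passing over the list alone, the scaffold gene Homer1 at -0.22 (SE 0.06). So did oligodendrocyte precursors (0.01, 0.835) with Gpr17 at -0.23 (SE 0.06) and neocortex (0.01, 0.737) with Scnn1a. Means were -0.05 for astrocytes (0.271), -0.06 for dentate granule cells (0.303), -0.08 for adult neurogenesis (0.465), -0.01 for mitochondrial biogenesis and dynamics (0.573) and 0.06 for imprinted genes (0.593). They were -0.04 for CA2 and CA3 pyramidal cells (0.593), 0.10 for meningeal fibroblasts (0.593), -0.02 for DNA methylation and histone modifiers (0.720), -0.03 for CA1 pyramidal cells (0.854) and -0.04 for striatum (0.854). GABAergic interneurons averaged -0.02 (0.912), choroid plexus 0.04 (0.912), erythrocytes -0.07 (0.932) and the citric acid cycle 0.0011 (0.932). Mean, median and test differed in sign for 3 lists. Immediate early genes had a median of -0.02, a mean of 0.01 and camera in the lower direction (0.912), mural cells -0.0011, 0.02 and the lower direction (0.932), and mitochondrially encoded mRNAs -0.02, 0.08 and the higher direction (0.983).

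The authors' deposited table of the offspring called 75 genes at an adjusted p under 0.1, 38 higher and 37 lower, and 11 under 0.05. All 75 were tested here with the same sign and an unadjusted p of at most 0.00882, and none passed with limma. At the table's adjusted p threshold of 0.1, DESeq2 called 54 of the 75 in the offspring alone and all 75 in the fit over all 23 libraries. The 10 named from that table, predicted genes passed over, included Tmem175, Zfp628 and Cry1 above. The others were Timm17a, a mitochondrial import gene, at -0.09 (SE 0.02), Med16, a Mediator subunit, at 0.19 (SE 0.04), Pnrc2 at -0.20, Zmiz2 at 0.13, Mis12, a kinetochore gene, at -0.18, the splicing factor Hnrnpl at 0.15 and the kinase Mast1 at 0.15. Timm17a had 3172 ± 33.2 normalized counts in offspring of exercised fathers (SD, n = 7) and 3381 ± 74.8 in offspring of sedentary fathers (n = 8). The authors' deposited enrichment table of the offspring gave nonsense-mediated decay (3 genes, 27.3-fold) a Benjamini-adjusted p of 0.798, mRNA processing (6 genes, 5.27-fold) one of 0.553 and circadian regulation of gene expression (3 genes, 13.9-fold) one of 0.861.

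Fold changes followed the GC content of genes in both generations. Across genes, which are not independent replicates, Spearman's rho of fold change with GC content was 0.381 in the fathers and 0.302 in the offspring. With genes in 10 equal bins by GC content, the lowest bin had a median log2 fold change of -0.08 in the fathers and -0.05 in the offspring, and the highest bin 0.08 and 0.06. The per-library GC slope, in log2 units per 10 percentage points of GC content, differed between groups by 0.07 in the fathers (exact permutation p = 0.171). In the offspring it differed by 0.04 (exact permutation p = 0.152). Of the authors' 75 offspring genes, the higher ones had a median GC content of 57.6% and the lower ones 43.9%, against 49.3% for all genes tested. Removing the GC trend was an alternative added after seeing the data. It took the number of genes at an unadjusted p under 0.05 from 1402 to 943 in the fathers. In the offspring that number went from 1726 to 1332. The smallest limma adjusted p was then 0.915 in the fathers and 0.542 in the offspring.

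**Figure D3:**
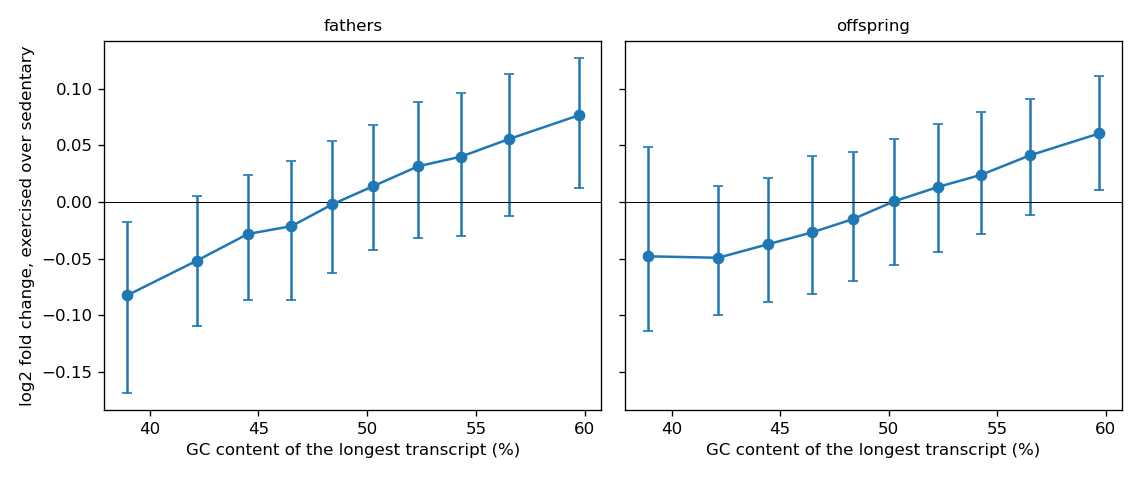
Median log2 fold change (exercised over sedentary) of tested genes against the median GC content (%) of their longest transcript, in 10 equal bins by GC content, for fathers (left) and offspring (right), with quartiles as bars. The median went from -0.08 to 0.08 in the fathers and from -0.05 to 0.06 in the offspring between the lowest and the highest bin.

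A further question was whether the genes that differed in the fathers differed in the same direction in the offspring. Over 17263 genes tested in both tables, the correlation of log2 fold changes was -0.04 (Pearson; exact permutation p = 0.543 over 70 labelings, the other 69 from -0.17 to 0.17). Spearman's rho was 0.10, of the other sign, and 57.1% of genes had the same sign in both. At an unadjusted p under 0.05 in both, 99 of 140 genes went the same way, 53 higher and 46 lower, where independent lists would share 33.8 and 34.3, and 41 went opposite ways, where they would share 69.97. Independent lists would share 138 genes in all, so the overlap of 140 differed from this in the direction of genes and hardly in their number, and fold changes followed GC content in the same direction in both generations. Genes are not independent and libraries were not permuted for these counts, so the excess in direction was not tested. Examples, chosen after their values were seen, were Erf at 0.16 in fathers and 0.24 in offspring, Tesk1 at 0.12 and 0.10, Zfp994 at -0.26 and -0.15 and Ptp4a1 at -0.11 and -0.11. Of the 21 and 75 genes called in the authors' deposited tables, 0 were shared.

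The 100 lower genes with the smallest p in the fathers averaged -0.05 in the offspring, 75 of them below 0, and camera gave p = 0.000524, or p = 0.402 with an estimated correlation. In each alternative that changed the fathers' fit, the 100 genes of each direction were chosen anew, so those values may describe other genes. With the GC trend removed, an alternative added after seeing the data, the mean of the 100 lower genes so chosen was 0.0098. Camera's p was 0.0626 without exercised fathers replicate 1, 0.268 without sedentary fathers replicate 1 and 0.0648 without replicate 7 of the offspring of exercised fathers, within a leave-one-out range from 3.53e-06 to 0.268. The 100 higher genes averaged -0.01, with 50 above 0, while camera pointed in the higher direction (p = 0.762, or p = 0.925 with an estimated correlation). For the higher genes chosen anew, the mean and camera's p were -0.11 and 0.0172 without exercised fathers replicate 2 and 0.04 and 0.00528 without exercised fathers replicate 3. They were -0.06 and 0.000354 with the GC trend removed. Over the libraries left out in turn, that p reached 0.899. A test of the difference between the generations' fold changes found 0 of 17263 genes with limma, with 984 at an unadjusted p under 0.05 and a smallest adjusted p of 0.718, and no other tool was run for it.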

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

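Chosen only after the results were seen were both tests of the choroid plexus pattern, the fits with thalamus and habenula covariates or without libraries that stood apart, and the removal of GC and length trends; the conditions of the shared dispersion test and of the first thalamus test were also made stricter then.

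Single libraries stood apart from the rest of their group by Dixon's criterion in 14 of 288 groups of values, and chance gives about 1 in 20. In exercised fathers replicate 1, Cs had 10391 normalized counts against 11409 to 11455 in the other libraries. Exercised fathers replicate 2 had 5232 for Arc against 3611 to 3757, 416 for Fos against 215 to 242, and a mean of 9.95 for immediate early genes against 9.45 to 9.53. In exercised fathers replicate 3, Pou4f1 had 16.1 against 1.04 to 3.02 and the glucocorticoid response mean was 10.48 against 10.33 to 10.34. Sedentary fathers replicate 1 had 507 for Tek against 549 to 552 and a microglia mean of 9.99 against 10.08 to 10.09. Pou4f1 had 158 in sedentary fathers replicate 2 against 2.54 to 22.2. In sedentary fathers replicate 4, Slc6a3 had 479 against 3.39 to 14.4 and Abhd12b 166 against 1.69 to 17.8. Among the offspring of exercised fathers, replicate 5 had a dentate granule cell mean of 11.01 against 10.73 to 10.84. Among the offspring of sedentary fathers, the oligodendrocyte and myelin mean of replicate 1 was 12.88 against 12.47 to 12.66, and the erythrocyte mean of replicate 6 was 10.37 against 6.02 to 7.77.

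Choroid plexus genes were higher on average in the exercised fathers, by 1.56 with an SD of 2.29 among sedentary libraries. Their 16 members moved as a block, with a median Spearman correlation of 1 between members over the 8 libraries, as varying amounts of choroid plexus in the dissected tissue would give. None of the 16 is in another list, and all 16 were above the filter even in the lowest library, while Ttr ran from 770 to 169193 normalized counts in the fathers and from 1136 to 187843 in the offspring. An effect of the fathers' exercise stays open, since the exact permutation p of the list mean was 0.314. Varying dissection is thus a candidate explanation for the difference, and the SD of 1.90 and 1.88 in both offspring groups is in line with it.

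The 20 genes that the authors' deposited table calls lower in exercised fathers include Shox2, Tnnt1 and Tcf7l2 of the thalamus and habenula list. With the mean of the 9 list members outside the table's calls, the 20 genes had a median Spearman correlation of 0.726 over the 8 fathers, and of 0.548 within groups, so tissue from thalamus, habenula or midbrain in some sedentary libraries may account for part of them, though 10 of the 12 members were above the filter in the lowest library as well. Over the 15 offspring libraries the correlation was 0.256 (permutation p = 0.0173), between the values that would argue for and against it. A DESeq2 fit with a dispersion shared over 4 groups called 2 of the 21 genes and the fit of the fathers alone 0, but 19 of the 21 had no adjusted p in the latter, so this test was void. A biological effect of exercise on these genes was not tested apart from it.

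The 75 genes of the authors' offspring table differed in GC content between the higher and the lower ones. Removing the GC trend took their median signed log2 fold change from 0.179 to 0.138, 77.2% of its value, and 65 of the 75 kept an unadjusted p under 0.05. GC content differences between libraries may therefore account for part of these fold changes but cannot be told apart from an effect of the fathers' exercise, because the GC slope did not separate the groups (exact permutation p = 0.152) and the value left lies between the bounds set. Removing the length trend left 0.178, 99.3% of the value, which argues against transcript length as the cause.

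For genes past the threshold the real count was 0 in both generations, which all 35 splits of the fathers and all 100 of the offspring reach by construction, so this count says nothing about chance. The highest other splits gave 26 genes in the fathers and 1 in the offspring. Chance could not be excluded for the other counts. For genes in the fathers at an unadjusted p under 0.05, 6 of 35 splits gave at least the real 1402, with 2121 as the highest other, and for lists 10 of 35 gave at least the real 9, with 15 as the highest other. In the offspring 11 of 100 splits gave at least the real 1726 genes at an unadjusted p under 0.05, with 3465 as the highest other, and all 100 at least the real 2 lists, with 15 as the highest other. The split with 26 genes set exercised fathers replicates 1, 2 and 4 and sedentary fathers replicate 2 against the rest, and that with 2121 set exercised fathers replicates 1 and 3 and sedentary fathers replicates 3 and 4 against the rest. In the offspring the split with 15 lists, several times the real 2, may point to a structure of the samples other than the groups, and what that split follows was not tested.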

How the results depend on the processing

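Chosen only after the results were seen were the fits with the thalamus and habenula covariate, alone or with the choroid plexus covariate, without sedentary fathers replicates 1 and 2 or 3 and 4, without the 5 offspring libraries low in choroid plexus genes, with GC or length trends removed, with all 23 libraries in DESeq2, and the exact permutation of list means.

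The cause of the changes given here was not tested, except that a covariate made from a list removes that list's own difference by construction. No paired analysis was possible because replicate numbers follow the order of accessions and pair no libraries. Of 1335 values of 50 named genes in the fathers, 1290 kept their direction and side of the threshold, 17 passed it and 28 changed sign, in 10 genes. In the offspring, of 1069 values of 31 genes, 1005 did, 26 passed and 38 changed sign, in 5 genes. No named gene passed in the main fit of either generation, so keeping the side of the threshold means only not passing again. Depth limits genes near the filter most, and reads are not independent molecules.

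The count of genes past the threshold in the fathers, 0 with limma (1402 at an unadjusted p under 0.05) and 0 with edgeR (1434), was 1 without sedentary fathers replicates 1 and 2 (Rora), 14 without sedentary fathers replicates 3 and 4 (13 higher, Slc4a5, Folr1, Kcnj13 and Kcne2 among them), 66 with DESeq2, 5 with DESeq2 over all 23 libraries, and 0 to 1 with each library left out. The sedentary libraries left out together stood apart in lists that hold these named genes, so those calls are no independent evidence. The 9 lists became 3 with array weights, 5 without the AD21 barcodes, 3 with the thalamus and habenula covariate, 4 with both covariates, 3 without sedentary fathers replicates 3 and 4, 0 by estimated correlation or fry, and 0 by exact permutation, where passing was hardly possible with 4 against 4 libraries. With a library left out they were 1 (sedentary fathers replicate 3) to 10 (sedentary fathers replicate 1), and under the other settings 6 to 10.

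Log2 fold changes in the fathers changed sign as follows. With the choroid plexus covariate Dcx was 0.068 and Fos -0.15. With the thalamus and habenula covariate Bdnf was -0.092, Slc6a3 0.41 and Tnnt1 0.22, and with both covariates Bdnf was -0.15, Cs 0.049 and Fos -0.34. With the GC trend removed Dcx was 0.038. Without sedentary fathers replicates 1 and 2 Dcx was 0.14, Fos -0.24, Slc4a5 -0.26, Aqp1 -0.28 and Folr1 -0.30, and without replicates 3 and 4 Bdnf was -0.076, Slc6a3 0.56 and Tnnt1 0.65. With each library left out, Bdnf ran from -0.044 to 0.091, Cs from -0.049 to 0.0020, Dcx from -0.11 to 0.054, Fos from -0.17 to 0.16, Vegfa from -0.085 to 0.020 and Slc6a3 from -2.04 to 0.22.

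In the offspring, the count of 0 genes with limma (1726 at an unadjusted p under 0.05) and with edgeR (1650) was 1 with array weights (Acer2), 48 with DESeq2, 91 with DESeq2 over all 23 libraries, and 0 to 1 with each library left out. The 2 lists became 1 with the filter at 50, 4 with quantile normalization (2 higher), 5 without the AD21 barcodes (2 higher), 6 with the thalamus and habenula covariate, 4 with the GC trend removed, 3 with title stems averaged (2 higher), 4 with the title stem as a block (2 higher), those higher being the nuclear respiratory chain and ribosomal proteins each time, 5 without the 5 libraries low in choroid plexus genes, and 0 by estimated correlation, fry or exact permutation. With each library left out they were 1 to 6.

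Fold changes in the offspring changed sign with array weights (Arc 0.035), without the AD21 barcodes (Dcx -0.024, Ppargc1a -0.020), with the thalamus and habenula covariate (Bdnf -0.025), with both covariates (Bdnf -0.011, Fos -0.027), with title stems averaged (Dcx -0.014, Ppargc1a -0.021, Fos -0.060), with the title stem as a block (Dcx -0.0028, Ppargc1a -0.0057, Fos -0.022) and without the 5 libraries low in choroid plexus genes (Fos -0.38). With each library left out, Arc ran from -0.17 to 0.15, Bdnf from -0.012 to 0.039, Dcx from -0.020 to 0.066, Fos from -0.20 to 0.33 and Ppargc1a from -0.0075 to 0.068.

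The correlation between generations, -0.04, was 0.10 by Spearman and 0.047 with the filter at 50, and ran from -0.15 to 0.055 with each library left out. Where the fathers' fit changed, the fathers' higher and lower genes were chosen anew. The offspring mean of the fathers' higher genes was -0.057 with the GC trend removed and ran from -0.11 to 0.038 with a library left out. For the fathers' lower genes it was -0.048 with an estimated correlation, where the call ended, -0.035 with the choroid plexus covariate, where it ended too, 0.0098 with the GC trend removed, and -0.081 to -0.012 with a library left out.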

Other observations

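The test of title stems was set before its result was seen, while the clock and neurogenesis genes and the test of Cry1 between generations were chosen for this part after their values were seen. None of these genes passed over all genes tested with limma. In the offspring Cry1 passed in the DESeq2 fit over all 23 libraries (adjusted p = 0.00901).

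Among clock genes, the estimates of Cry1, Per2, Per3 and Tef were above 0 in the fathers and below 0 in the offspring, and those of Nr1d2, Bhlhe41 and Hlf were below 0 in both, while the clock list passed in neither generation. Cry1, a repressor of the circadian clock, had 709 ± 53.4 normalized counts in exercised and 620 ± 32.0 in sedentary fathers (SD, n = 4 each; log2 fold change 0.19, SE 0.07). Its log2 fold change in the offspring was -0.26 (SE 0.06). Per2 stood at 0.18 (SE 0.11) in the fathers and -0.20 (SE 0.08) in the offspring, Per3 at 0.19 (SE 0.06) and -0.03 (SE 0.06), and Tef at 0.11 (SE 0.04) and -0.09 (SE 0.04). Nr1d2 stood at -0.01 (SE 0.04) and -0.15 (SE 0.05), Bhlhe41 at -0.03 (SE 0.06) and -0.13 (SE 0.05), and Hlf at -0.14 in both. The test of the difference between generations gave 0.45 for Cry1 (limma adjusted p = 0.718, as small as any of the 17263 genes), and labels give no time of day at which tissue was collected.

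Some genes of adult neurogenesis, the birth of neurons in the dentate gyrus, also had estimates of opposite sign, though this list too passed in neither generation and no gene passed the test of the difference. Eomes, a factor of intermediate progenitors, had 145 ± 99.1 normalized counts in exercised and 38.5 ± 28.9 in sedentary fathers (SD, n = 4 each; log2 fold change 1.82, SE 0.69). In the offspring it had 68.7 ± 26.7 (SD, n = 7) and 104.9 ± 39.7 (n = 8), a log2 fold change of -0.61 (SE 0.27). The proliferation gene Top2a had 40.7 ± 2.34 and 25.3 ± 6.20 in the fathers (0.70, SE 0.20) and a log2 fold change of -0.10 (SE 0.13) in the offspring, where Mki67, another proliferation gene, stood at -0.27 (SE 0.11), against 0.07 (SE 0.25) in the fathers. Hopx, a marker of neural stem cells and astrocytes, stood at 0.25 (SE 0.07) in the fathers and -0.12 (SE 0.05) in the offspring. Among glutamatergic synapse genes in the fathers, the receptor gene Gria4 stood at -0.18, and Camk2b and Dlg4 at 0.11 and 0.10.

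A hypothesis written before the test was that offspring libraries whose titles agree but for the last number resemble each other. The 3 such pairs among the offspring of exercised fathers had residual correlations of 0.213, 0.0763 and 0.260, a mean of 0.183, against a mean of -0.220 for the other pairs. Subtracting the mean of the same libraries pulls such correlations below 0 by construction, so the negative mean does not show that those pairs are opposed. Of all ways to pick 3 disjoint pairs among these 7 libraries, 2 gave a mean as high, the real one included, with 0.198 for the other. The labels do not say what the shared part of a title stands for, so a shared father or litter is a possible explanation that was not tested. Apart from the fits that averaged or blocked title stems, the offspring tests treated all libraries as independent. If libraries with a shared stem are related, those p-values and the SDs given with n = 7 overstate the independence of the offspring of exercised fathers.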
